A study of Mus musculus with 27 samples.

How the data were processed

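The values analysed were raw read counts per gene in 27 libraries, as deposited by the authors. Per the labels, RNA from cultured macrophages was selected by poly(A) and made into libraries with the NEBNext Ultra II Directional kit, and paired reads of 50 bp were made on an Illumina NovaSeq. Per the submitters' processing notes, reads were trimmed with fastp 0.23.2, aligned to the mouse genome build mm10 (GRCm38) with STAR 2.7.0 and counted with featureCounts, whose version was not stated. These notes also named edgeR 3.38.4 for the submitters' tests. The strand setting used in counting is not given in the sources used here. Values of genes that overlap another gene, have an antisense partner or share near-identical copies (such as the paired Ig-like receptors Pilra, Pilrb1 and Pilrb2 or the MHC class II genes) are therefore less certain.

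The deposited count table held 29872 genes. Gene positions came from GENCODE vM21 on GRCm38, in which 29815 of the gene identifiers were found and 57 were not. Genes with too few counts were left out with filterByExpr (minimum count 10, groups as in the design), which left 14589 genes. Library sizes were scaled by TMM. All 27 libraries entered 1 model with a mean for each of the 8 groups of genotype and treatment, and each comparison was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, legacy dispersion, robust), adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.122. Log2 fold changes are the fitted values with their standard error (SE), and CPM is edgeR's count of a gene relative to the scaled library size. For an interaction, the value is the log2 fold change of the treatment in knockout cells minus that in wild-type cells. The design, the tests and 28 gene lists were fixed before the data were examined.

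The lists held known IL4 and alternative activation genes, glucocorticoid receptor targets, proinflammatory cytokines with NF-kappaB genes, interferon-stimulated genes, MHC class II presentation, efferocytosis and scavenging, fatty acid oxidation and storage, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, the integrated stress response, immediate early genes, the cell cycle, matrix remodelling, chemokine and cytokine receptors, nuclear receptor coregulators, macrophage identity, and markers of osteoclasts, monocytes, neutrophils, dendritic cells, B cells, T and NK cells, mast cells, erythroid cells, endothelial cells and stromal cells. Each list was tested against all other genes with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 28 lists, and again with a correlation estimated from the data. Where a call given with camera's adjusted p was lost with an estimated correlation, that adjusted p follows it, and the other calls so given held. For each list the number of called genes is also given when p-values were adjusted over the list alone.

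The genes named were chosen by a rule fixed beforehand. For each treatment against vehicle these were the 6 largest rises and 6 largest falls in fitted log2 fold change among called genes with at least 5 CPM in the higher group and no overlap between the libraries of the groups (predicted genes and clone names left out), and for other comparisons the 5 largest of each (for interactions without the last condition). For genes shared by both treatments, the 6 rises and 6 falls with the largest smaller change were taken. Each list was represented by up to 4 members with the smallest adjusted p. Ncoa2, Ncoa1, Ncoa3, Nr3c1, Stat6, Klf4, Lyz2, Fkbp5, Tsc22d3, Arg1, Chil3, Retnla and Mrc1 were always included. From these sets, genes whose call did not hold when 1 library was left out are mostly not named, or given with that value. Some genes that the rule selected are not reported here. Where a group held 0 counts of a gene, a fold is a lower bound from a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio has a 95% exact interval. These bounds and intervals cover counting error only.

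The libraries of the groups carried replicate numbers, 1 to 3 in wild type and 1 to 4 in knockout, with 1, 2 and 4 in the knockout IL4 group. The labels do not say what a number shares. Across genes, the correlations of same-numbered libraries' deviations from their group means were 0.56 to 0.77 for IL4 and vehicle in wild type, 0.62 to 0.75 for corticosterone and vehicle, 0.55 to 0.71 for dexamethasone and vehicle, 0.54 to 0.74 for both glucocorticoids, 0.55 to 0.75 for IL4 and corticosterone and 0.46 to 0.59 for IL4 and dexamethasone. In knockout they were 0.11 to 0.47 for corticosterone and vehicle and 0.33 to 0.56 for both glucocorticoids. Each of these passed the rule of over 0.1 in every pair, so a fit with the replicate number as a block is given beside a result where it moved a count by over 1.5 times.

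Alternatives fixed beforehand were RLE scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, the edgeR 4 form of the quasi-likelihood fit, a fit of only the groups compared, the replicate block, leaving out each library in turn, an estimated correlation in camera, the fry test for lists, a 2-fold minimum for shared calls and a split of the vehicle libraries for shared calls. A further 2 were chosen after the data were seen, without the 4 libraries that held over 50 CPM of Arg1 outside the IL4 groups and without the 4 wild-type libraries numbered 1.

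The steps were first run on simulated counts with known changes, with the means, dispersions and library sizes of the real data. For IL4 against vehicle in wild type (3 against 3 libraries), 59.7% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 2.87% of calls false. For dexamethasone against vehicle in knockout (4 against 4), the shares were 80.6%, 94.0% and 95.5% for the same folds, with 4.76% false. For knockout against wild type with vehicle (4 against 3), they were 70.1%, 91.0% and 98.5%, with 3.89% false. For the interaction of genotype and dexamethasone, they were 55.2%, 77.6% and 95.5%, with 5.59% false. The simulated list of changed genes was called in each, and 0 random lists were.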

Results

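Gene expression was measured by poly(A) RNA sequencing in macrophages grown for 5 days from the bone marrow of male mice 8 to 10 weeks old, in medium with 10% L-cell conditioned medium as the source of macrophage growth factor. The libraries came from wild-type mice (12 libraries) and from mice lacking GRIP1 in myeloid cells (15 libraries). GRIP1, encoded by Ncoa2, is a coregulator that binds the glucocorticoid receptor and other transcription factors. In the knockout, Cre recombinase made from the Lyz2 (LysM) locus removes a floxed part of Ncoa2. Cells of both genotypes received vehicle, interleukin 4 (IL4) at 10 ng/ml, corticosterone at 500 nM or dexamethasone at 100 nM for 24 h. IL4 drives the alternative activation of macrophages, corticosterone is the main natural glucocorticoid of mice, and dexamethasone is a synthetic glucocorticoid. Each wild-type group held 3 libraries, the knockout IL4 group 3, and the other knockout groups 4. The design asks which genes each treatment changes, which are shared, and how responses differ without GRIP1. Libraries held 20162729 to 48023102 counts in genes. The labels do not say which libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The genotype given in the sample labels of the wild-type animals is LysM-Cre with wild-type GRIP1, while the sample titles and the series text give BL6.

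Ncoa2 (ENSMUSG00000005886, GRCm38 chromosome 1, 13139105 to 13374083, minus strand) was lower in every knockout library than in any wild-type library. Its level was 55.7, 71.4 and 72.0 CPM in wild-type libraries with vehicle, 59.0, 68.6 and 62.3 with IL4, 76.5, 87.7 and 75.2 with corticosterone, and 76.4, 93.4 and 89.2 with dexamethasone. In knockout libraries Ncoa2 was at 19.0, 16.1, 16.7 and 22.2 CPM with vehicle, 17.1, 20.3 and 26.0 with IL4, 17.2, 19.7, 18.9 and 25.2 with corticosterone, and 18.9, 24.9, 18.9 and 25.8 with dexamethasone. The fitted log2 fold change of Ncoa2, knockout against wild type, was −1.85 ± 0.15 (SE, adjusted p = 9.52e-09) with vehicle, −1.59 ± 0.16 (6.06e-07) with IL4, −1.98 ± 0.15 (2.53e-09) with corticosterone and −1.96 ± 0.15 (1.89e-09) with dexamethasone. Counts were summed over the whole gene, so transcripts that lack only the floxed part still add to them. Counts left in knockout thus do not tell how complete the loss of GRIP1 was. Lyz2 (chromosome 10, 117277331 to 117282321), the locus that carries Cre, was at 39.0 ± 9.69 CPM (SD, n = 3) in wild-type and 33.2 ± 6.31 CPM (SD, n = 4) in knockout cells with vehicle, which did not differ by edgeR's test.

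**Figure D1:**
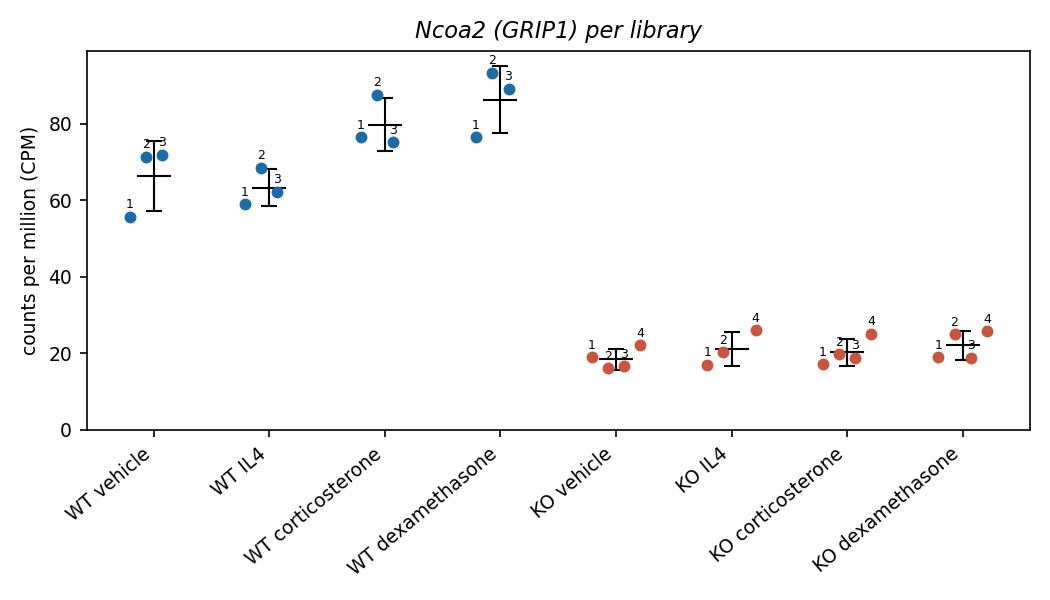
Ncoa2 in CPM (y axis) in each of the 27 libraries by genotype and treatment (x axis), with replicate numbers, group means and SD bars. Wild-type libraries lie between 55.7 and 93.4 CPM, and knockout libraries between 16.1 and 26.0 CPM.

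IL4 raised the genes that mark alternatively activated macrophages in wild-type cells. Retnla, which encodes a secreted resistin-like protein (chromosome 16, 48842551 to 48844461), had 0 counts in the vehicle libraries and 188 ± 68.1 CPM (SD, n = 3) with IL4, at least 5700-fold more. Arg1, the enzyme that turns arginine into ornithine (chromosome 10, 24915221 to 24927484), rose from 2.36 ± 1.29 to 870 ± 80.1 CPM (log2 fold change 8.55 ± 1.77, adjusted p = 0.000786). The lectin Mgl2 rose by 9.25 ± 1.46 and the ligand of PD-1 Pdcd1lg2 by 7.97 ± 0.78. Other large rises were those of Msx3 (at least 1140-fold), Kcnd3 (1980-fold, interval 354 to 78100) and Scn3a (1760-fold, interval 316 to 69600). The transcription factor Irf4 rose by 5.42 ± 0.42 (adjusted p = 3.68e-09), the chemokine Ccl24 by 5.85 ± 0.50 and the mannose receptor Mrc1 by 2.03 ± 0.21. The largest fall was that of the fractalkine receptor Cx3cr1 (chromosome 9, 119901616 to 120069879), from 204 ± 61.2 to 2.75 ± 1.02 CPM (−6.19 ± 0.71, adjusted p = 9.14e-07). Other falls were those of the formyl peptide receptors Fpr1 (−4.37 ± 0.56) and Fpr2 (−3.64 ± 0.44), Nfkbiz (−3.37 ± 0.34), Marcksl1 (−3.32 ± 0.32) and the bacterial lipoprotein receptor Tlr2 (−3.26 ± 0.33). In all, IL4 raised 2163 and lowered 2225 of 14589 genes, and 1137 of them moved at least 2-fold.

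Of 32 known IL4 and alternative activation genes, 28 rose, 2 fell (the receptor chain Il4ra, and Jag2, whose adjusted p was 0.0555 without the vehicle library numbered 3) and 2 did not pass, with the same numbers adjusted over the list alone. Their median log2 fold change was 4.18, which stays the same with Retnla at its lower bound (camera adjusted p = 3.24e-18, and adjusted p = 0.105 with an estimated correlation). MHC class II genes present antigen to T cells, and of 11 of them 9 rose and 1 fell (9 and 1 adjusted over the list alone). Among the rises were their master regulator Ciita (4.51 ± 0.33), H2-DMa (2.30 ± 0.19) and H2-Ab1 (2.26 ± 0.23). This list's median was 1.58 (camera adjusted p = 4.21e-07). Of 24 genes of fatty acid oxidation and storage, which alternatively activated macrophages use as fuel, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 3.42e-08). Among the rises was Ppargc1b (1.77 ± 0.16). Osteoclast and fusion genes rose in 8 of 10 cases (8 adjusted over the list alone), with Ocstamp at 3.52 ± 0.22 and Dcstamp at 1.89 ± 0.28 (camera adjusted p = 5.05e-06). Cell cycle genes went down by small amounts, 36 of 40 of them (37 adjusted over the list alone) with a median of −0.49, as in Ube2c (−0.82 ± 0.14) and Aurka (−0.72 ± 0.12; camera adjusted p = 2.6e-11, 0.585 with an estimated correlation). Of 24 cholesterol synthesis genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), such as Dhcr7 (1.01 ± 0.11; camera adjusted p = 9.38e-05, 0.585 with an estimated correlation). Interferon-stimulated genes fell in 20 and rose in 3 of 36 cases (24 and 3 adjusted over the list alone), with Rtp4 at −2.85 ± 0.53 and Usp18 among the rises at 1.29 ± 0.24 (camera adjusted p = 0.000909, 0.751 with an estimated correlation). Proinflammatory genes fell in 13 and rose in 2 of 27 cases (13 and 2 adjusted over the list alone), with Tnf at −2.04 ± 0.20 and the inflammasome gene Nlrp3 at −1.91 ± 0.15 (camera adjusted p = 0.00239, 0.585 with an estimated correlation).

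Arg1 separated 4 libraries that had not received IL4 from the rest of their groups. With vehicle, the knockout libraries numbered 2 and 3 held 117 and 78.4 CPM of Arg1, and those numbered 1 and 4 held 2.63 and 4.27. With dexamethasone, the wild-type library numbered 1 held 67.1 CPM of Arg1 against 0.993 and 2.07 in the others, and the knockout library numbered 2 held 68.0 against 0.277, 0.820 and 12.2. In the IL4 groups Arg1 lay between 491 and 947 CPM. The lectin Mgl2 was at 17.5 ± 17.4 CPM (SD, n = 4) in knockout cells with vehicle and at 0.163 CPM in wild-type cells with vehicle. Some results that moved without these 4 libraries are given with both values, while others are not.

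**Figure D2:**
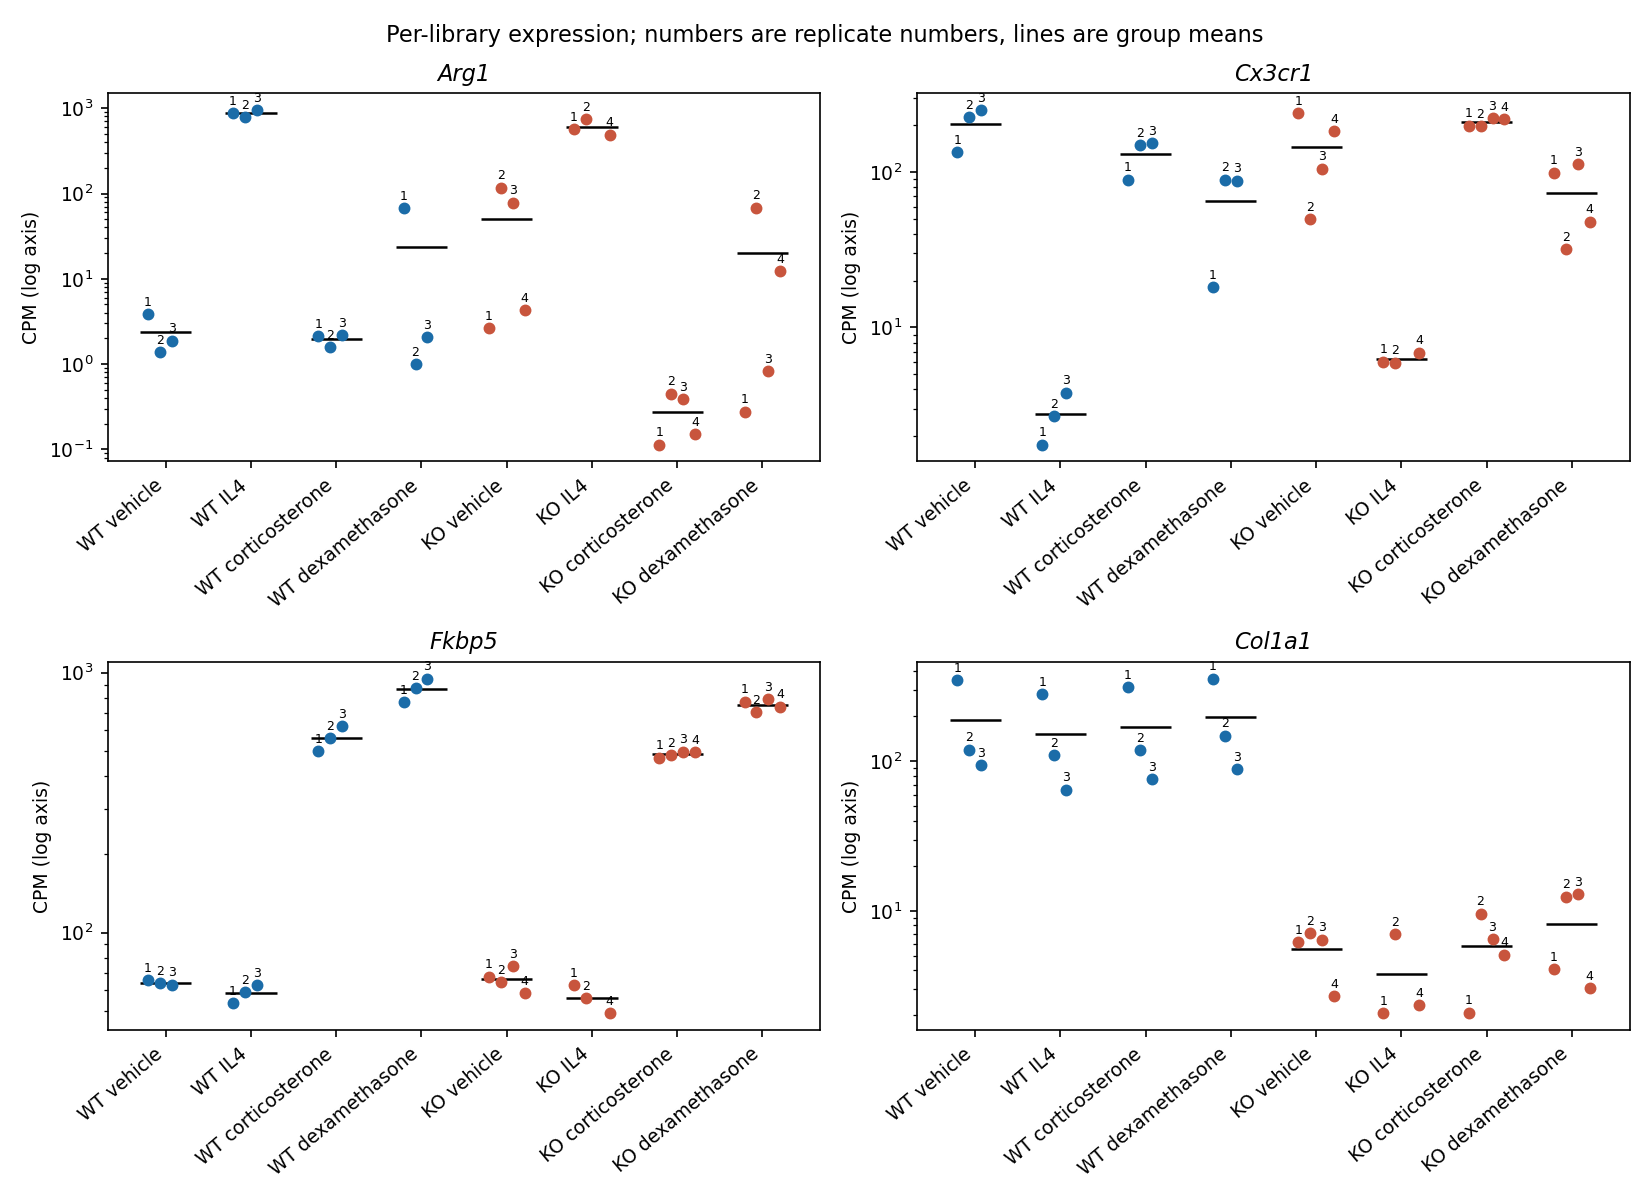
Arg1, Cx3cr1, Fkbp5 and Col1a1 in CPM (y axis, log scale) in each of the 27 libraries by genotype and treatment (x axis), with replicate numbers and lines at group means. Arg1 is at 491 to 947 CPM in IL4 libraries and at 67.1 to 117 CPM in 4 libraries without IL4.

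Corticosterone raised classical targets of the glucocorticoid receptor in wild-type cells. The receptor chaperone gene Fkbp5 (chromosome 17, 28399094 to 28517527) rose from 64.1 ± 1.36 to 561 ± 62.2 CPM (SD, n = 3; log2 fold change 3.13 ± 0.10, adjusted p = 2.26e-16). The zinc finger gene Zbtb16 (chromosome 9, 48654297 to 48836222) rose by 4.11 ± 0.26 and the haemoglobin scavenger receptor Cd163 by 3.16 ± 0.25. Klf9 (chromosome 19, 23141226 to 23168134) rose by 3.07 ± 0.14 and Tsc22d3, which encodes the anti-inflammatory protein GILZ (chromosome X, 140539528 to 140600659), by 2.07 ± 0.12. The tetraspanin-like Ms4a4a (chromosome 19, 11375523 to 11392790) rose by 3.35 ± 0.24 and the sulphotransferase Sult1a1 by 2.97 ± 0.35. Falls included those of the cholesterol hydroxylase Ch25h (−3.15 ± 0.38), Acod1, which makes itaconate (−2.23 ± 0.36), the paired receptors Pilra (−2.12 ± 0.29) and Pilrb1 (−1.86 ± 0.32) and the niacin receptor Hcar2 (−1.95 ± 0.30). Corticosterone raised 507 and lowered 359 genes, 210 of them at least 2-fold. These 866 calls became 497 without the corticosterone library numbered 2, 561 without the one numbered 3, 486 without the 4 wild-type libraries numbered 1, and 1790 with the replicate number as a block.

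Of 30 glucocorticoid receptor targets listed beforehand, 9 rose and 3 fell with corticosterone (10 and 4 adjusted over the list alone; camera adjusted p = 4.3e-06). Genes for the uptake of dead cells and scavenging rose in 9 of 27 cases and fell in 1 (14 and 3 adjusted over the list alone; camera adjusted p = 7.2e-06). Among them were the apoptotic cell receptor Mertk (1.34 ± 0.12) and Stab1 (0.84 ± 0.13). Proinflammatory and NF-kappaB genes fell in 11 of 27 cases and rose in 1 (12 and 1 adjusted over the list alone), with Il1b at −2.79 ± 0.40, Traf1 at −1.33 and Icam1 at −0.87 ± 0.07 (camera adjusted p = 2.34e-09). B cell transcripts fell in 5 of 6 cases (5 adjusted over the list alone), with a median of −1.01 (camera adjusted p = 8.79e-05). Interferon-stimulated genes fell in 5 and rose in 2 of 36 cases (16 and 2 adjusted over the list alone), and Ifi204 went against the list at 0.89 ± 0.12 (camera adjusted p = 2.73e-06, 0.643 with an estimated correlation).

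Dexamethasone also raised the receptor targets Zbtb16, Klf9, Cd163 and Fkbp5. In wild-type cells a large rise was that of Jaml, which encodes a junctional adhesion molecule, from 0.303 to 23.3 ± 8.69 CPM (SD, n = 3; 6.25 ± 0.33, adjusted p = 2.27e-12). Zbtb16 rose by 5.40 ± 0.26, Ms4a4a by 4.28 ± 0.25, Sult1a1 by 4.16 ± 0.35, the stress gene Ddit4 by 4.13 ± 0.43, Klf9 by 3.83 ± 0.14 and Cd163 by 3.59 ± 0.25. Fkbp5 rose by 3.75 ± 0.10 (adjusted p = 6.33e-18), and Mrc1 by 1.44 ± 0.21 (adjusted p = 3.27e-05). Genes that fell included Ch25h (−4.21 ± 0.42), Acod1 (−3.09 ± 0.39), Pilra (−2.81 ± 0.30), Hcar2 (−2.68 ± 0.32), Pilrb1 (−2.62 ± 0.34) and the NF-kappaB inhibitor Tnip3 (−2.52 ± 0.12). Dexamethasone raised 1117 and lowered 879 genes, 470 of them at least 2-fold. The 1996 calls became 1327 without the dexamethasone library numbered 3, 1329 with only the groups compared in the fit and 3225 with the replicate number as a block.

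Among receptor targets 10 of 30 rose and 4 fell with dexamethasone (11 and 5 adjusted over the list alone; camera adjusted p = 4.34e-06). Efferocytosis and scavenging genes rose in 13 and fell in 2 of 27 cases (15 and 4 adjusted over the list alone), with Mertk at 1.53 ± 0.12 and Stab1 at 1.02 ± 0.13 (camera adjusted p = 9.06e-05). Proinflammatory genes fell in 14 and rose in 2 of 27 cases (15 and 2 adjusted over the list alone), including Cxcl3 (−3.06 ± 0.44), Il1b (−3.02 ± 0.42) and Icam1 (−1.07 ± 0.07; camera adjusted p = 4.36e-08, 0.0694 with an estimated correlation). B cell transcripts fell in 5 of 6 cases (5 adjusted over the list alone), such as Cd79b (−1.49 ± 0.21) and Blnk (−0.55 ± 0.10; camera adjusted p = 0.000296, 0.0694 with an estimated correlation).

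Corticosterone and dexamethasone were compared directly, at doses that were not matched. In wild-type cells 840 genes were called with both, out of 2022 called with either. The change was larger with dexamethasone in 785 (93.5%) of the 840, with a median absolute log2 fold change of 0.744 against 0.569. A direct test called 27 genes, 22 higher and 5 lower with dexamethasone, with 541 genes at an unadjusted p under 0.05. Jaml (2.43 ± 0.24, adjusted p = 5.23e-06), the kinase inhibitor Pik3ip1 (1.51 ± 0.23), Zbtb16 (1.29 ± 0.20), Tns1 (0.71 ± 0.11) and Fkbp5 (0.62 ± 0.09, adjusted p = 0.00229) were higher. The B cell coreceptor Cd72 (−0.73 ± 0.11) and Tnip3 (−0.76 ± 0.12) were lower. Without the wild-type libraries numbered 1, Tnip3 was at −0.68 (adjusted p = 0.0969). The 27 calls became 10 without the corticosterone library numbered 1, 16 without the one numbered 2 and 15 without the dexamethasone library numbered 3. They were 53 without the 4 libraries high in Arg1, 14 without the wild-type libraries numbered 1, 10 with only the groups compared in the fit, and 137 with the replicate block. The edgeR 4 fit called 42 and DESeq2 57. In knockout cells 1497 genes were called with both of 2949 called with either, 1081 (72.2%) changed more with dexamethasone, and the direct test called 47, with 26 higher and 21 lower. Jaml was again higher (2.41 ± 0.19, adjusted p = 1.49e-07), with Pik3ip1 at 1.73 ± 0.20, Zbtb16 at 1.38 ± 0.18, Klf9 at 0.96 ± 0.11 and Fkbp5 at 0.63 ± 0.08, and Tnip3 was at −1.09 ± 0.11. These 47 calls became 27, 24 and 31 without the knockout corticosterone libraries numbered 1, 2 and 3, 19 without the dexamethasone library numbered 4, 101 without the 4 libraries high in Arg1, 80 with only the groups compared in the fit, 274 with the block and 164 by DESeq2. Of receptor targets, 4 of 30 were higher and 0 lower with dexamethasone in wild type (7 and 1 adjusted over the list alone, camera adjusted p = 4.64e-09). In knockout 5 were higher and 0 lower (8 and 2 adjusted over the list alone, camera adjusted p = 4.67e-05).

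Set directly against each other in wild-type cells, IL4 and the glucocorticoids separated the marker genes of both programmes. IL4 gave higher Retnla (16600-fold over corticosterone, interval 2980 to 657000, and 7120-fold over dexamethasone, interval 1970 to 58800), higher Pdcd1lg2 (8.41 ± 0.83 over dexamethasone) and higher Ciita (6.57 ± 0.41 over corticosterone and 6.24 ± 0.40 over dexamethasone). It gave lower Zbtb16 (−4.79 ± 0.28 and −6.09 ± 0.28), the coagulation factor gene F13a1 (−4.74 ± 0.48 and −5.21 ± 0.48) and the thymic protease gene Prss16 (−4.64 ± 0.43 and −5.24 ± 0.43). Also lower was Cd163 (−4.46 ± 0.28 and −4.89 ± 0.28). Fkbp5 was at −3.26 ± 0.10 and −3.88 ± 0.11. Jaml was lower than with dexamethasone (−6.33 ± 0.34) and Cx3cr1 lower than with corticosterone (−5.56 ± 0.69). IL4 against corticosterone called 2162 genes higher and 2466 lower, and IL4 against dexamethasone 2182 higher and 2437 lower. In both, 29 of 32 IL4 genes were higher and 2 lower (29 and 2 adjusted over the list alone), with camera adjusted p = 1.93e-18 against corticosterone and 3.31e-16 against dexamethasone (adjusted p = 0.0812 and 0.117 with an estimated correlation). MHC class II genes were higher in 8 of 11 cases in both comparisons and lower in 0 (9 and 8 higher adjusted over the list alone), with camera adjusted p = 6.5e-07 and 9.6e-07. Receptor targets were lower in 15 of 30 cases in both and higher in 4 and 5 (15 lower in both adjusted over the list alone, with 7 and 6 higher; camera adjusted p = 0.000722 and 0.000104). Cholesterol synthesis genes were higher in 15 and 13 of 24 cases and lower in 0 (16 and 14 higher adjusted over the list alone; camera adjusted p = 6.74e-07 and 1.1e-05, 0.319 and 0.348 with an estimated correlation).

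Some genes moved in the same direction with IL4 and with glucocorticoid, the question posed by the series title. The transcription factor Klf9 rose in wild-type cells from 4.74 ± 0.08 CPM with vehicle to 27.1 ± 0.86 with IL4, 39.8 ± 1.92 with corticosterone and 67.3 ± 1.67 with dexamethasone (SD, n = 3). Ms4a4a rose by 2.86 with IL4, 3.35 with corticosterone and 4.28 with dexamethasone. The serotonin receptor Htr2a rose by 2.45 ± 0.28, 1.63 ± 0.29 and 2.41 ± 0.29, and the carbonyl reductase Cbr2 by 1.51 ± 0.26 with IL4 and 1.92 ± 0.26 with corticosterone. With IL4 and dexamethasone the GTPase Rab15 rose by 3.68 ± 0.71 and 4.84 ± 0.71, and Ccl24 by 5.85 ± 0.50 and 2.81 ± 0.58. Shared falls were those of Pilra (−3.2 ± 0.31 with IL4), Pilrb1 (−2.35 ± 0.33) and Pilrb2 (−2.70 ± 0.32), and of Hcar2 (−1.46 ± 0.29). The fatty acid receptor Gpr84 also fell (−2.66 ± 0.25 with IL4, −1.45 ± 0.24 with corticosterone and −2.22 ± 0.25 with dexamethasone).

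In wild type 345 genes were called in one direction with IL4 and corticosterone (165 up, 180 down, where independent lists would share 75.2 and 54.8), and 153 in opposite directions (independent 130.5). With IL4 and dexamethasone the shared genes were 755 (346 up and 409 down, independent 165.6 and 134.1), and the opposite ones 301 (independent 300.7). Both glucocorticoids shared 840 genes (499 up and 341 down, independent 38.8 and 21.6), with 0 opposite. All comparisons used the same vehicle libraries, and groups simulated without any effect against them shared 0 calls in each of 20 runs, a value that says nothing of how many genes unrelated responses would share. The covariance of fold changes was 0.0414 for IL4 and corticosterone (simulated 0.0386, difference 0.0028), 0.1006 for IL4 and dexamethasone (0.0385, difference 0.0621) and 0.1833 for both glucocorticoids (0.0387, difference 0.1446). Pearson's r across genes was 0.133, 0.25 and 0.845 against simulated medians of 0.487, 0.479 and 0.484. The simulated libraries were drawn without the correlation of same-numbered libraries, so the differences of covariance, here and in knockout, may be off. The 3 wild-type vehicle libraries cannot be split into parts of 2, so part of the excess may come from the shared controls. The 345 became 210 without the vehicle library numbered 3, 201 and 227 without the corticosterone libraries numbered 2 and 3, and 175 without the wild-type libraries numbered 1, which gave 489 and 478 for the 755 and the 840. The 840 became 492 and 552 without the corticosterone libraries numbered 2 and 3. With the replicate block the 3 counts were 746, 1329 and 1701.

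**Figure D3:**
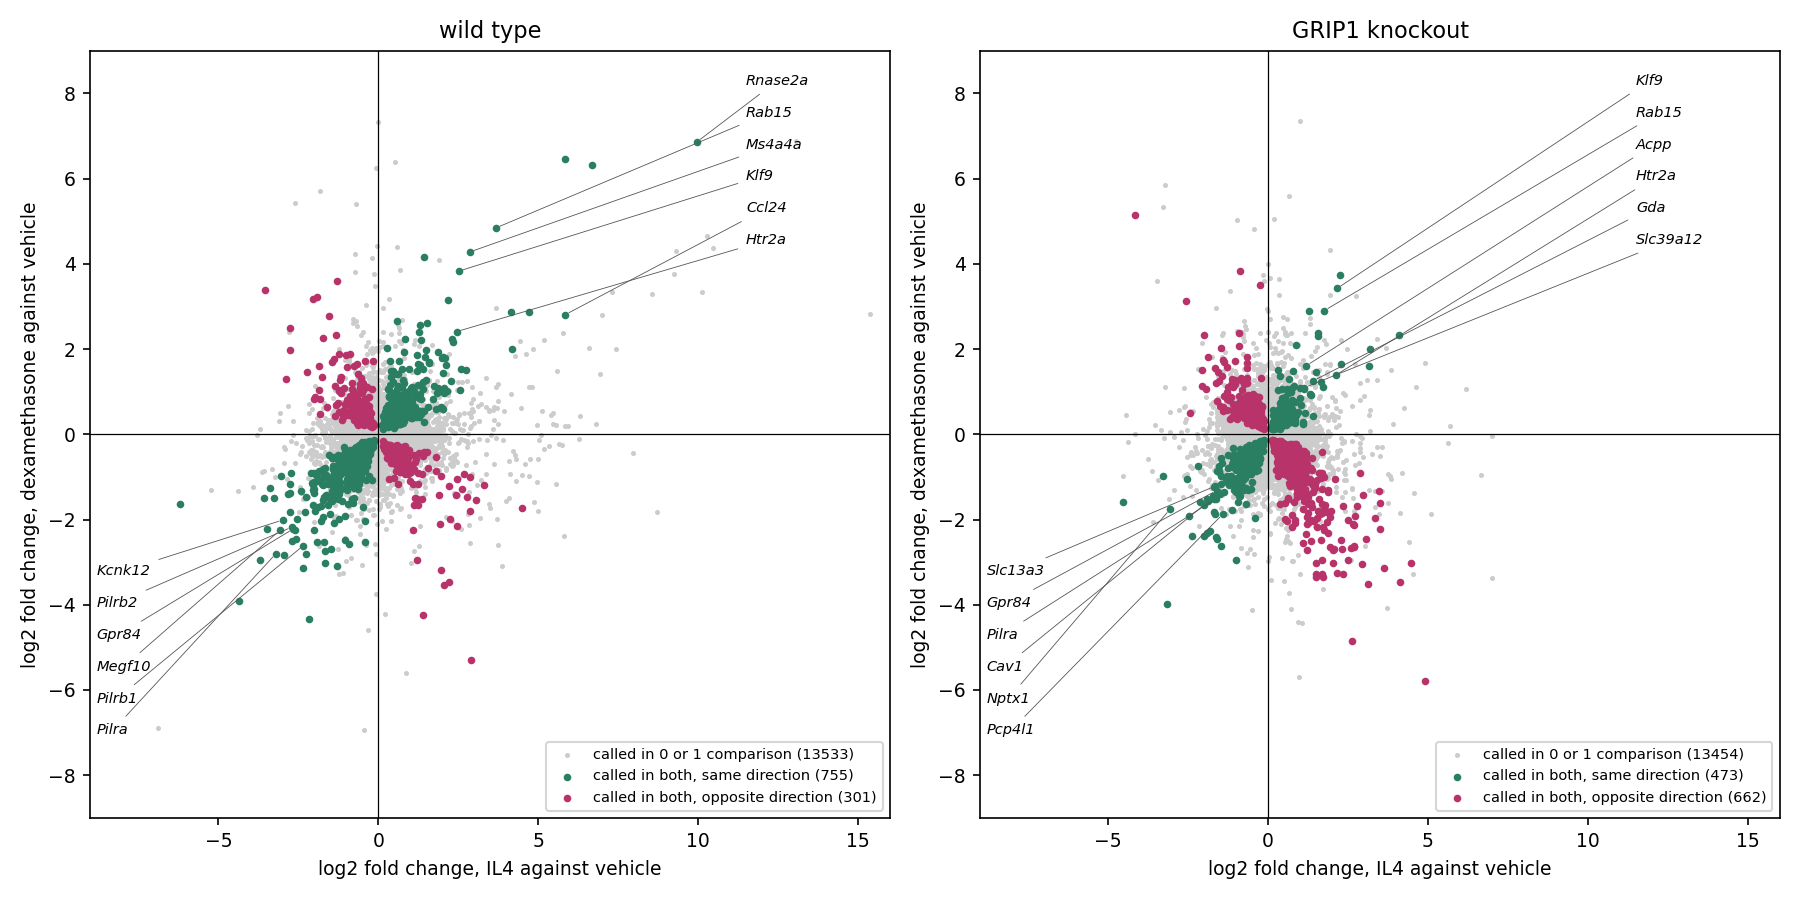
Log2 fold change with dexamethasone (y axis) against that with IL4 (x axis), each against vehicle, for every gene tested, in wild-type and in knockout cells, with colours for genes called in both and names for selected shared changes. In wild type 755 genes moved in one direction and 301 in opposite directions, and in knockout 473 and 662.

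IL4 still raised its marker genes in the knockout. In knockout cells Retnla rose from 1.87 ± 2.87 CPM (SD, n = 4) to 221 ± 18.9 CPM (SD, n = 3; adjusted p = 3.42e-07). Irf4 rose by 3.49 ± 0.32, Cish, a feedback inhibitor of cytokine signals, by 4.18 ± 0.42, the chitinase-like gene Chil3 by 4.64 ± 0.70, and Mrc1 by 0.88 ± 0.19. Other large rises were in Tuba8 (5.69 ± 0.47) and Ccn3 (5.62 ± 0.45). Cx3cr1 fell by 4.52 ± 0.63, Fpr1 by 3.35 ± 0.60, Nptx1 by 3.07 ± 0.42 and Marcksl1 by 2.67 ± 0.31. Arg1 was at 50.6 ± 56.8 CPM with vehicle and 601 ± 128 with IL4 (3.57 ± 1.19, adjusted p = 0.0314), and its adjusted p was 0.0723 and 0.0758 without the vehicle libraries numbered 1 and 4, and 0.06 without the IL4 library numbered 2. Without the 4 libraries high in Arg1 its log2 fold change was 7.41. In all, 2120 genes rose and 1753 fell, 716 of them at least 2-fold, and with only the groups compared in the fit the 3873 calls became 1745. Of IL4 genes 28 of 32 rose and 2 fell (29 and 2 adjusted over the list alone), with a median of 2.38 (camera adjusted p = 1.82e-19, 0.0854 with an estimated correlation) that was 3.70 without the 4 libraries high in Arg1. MHC class II genes rose in 8 of 11 cases and fell in 1 (8 and 1 adjusted over the list alone), with Ciita at 2.35 ± 0.25 and H2-DMa at 1.49 ± 0.16 (camera adjusted p = 6.77e-06, 0.0854 with an estimated correlation). Cell cycle genes fell in 28 of 40 cases (34 adjusted over the list alone; camera adjusted p = 2.8e-11, 0.619 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 24 cases (14 adjusted over the list alone; camera adjusted p = 4.44e-06, 0.501 with an estimated correlation). Fatty acid genes rose in 12 of 24 (14 adjusted over the list alone; camera adjusted p = 7.27e-05).

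Glucocorticoid receptor targets rose in the knockout as well. With corticosterone, Fkbp5 rose in knockout cells from 66.2 ± 6.47 to 486 ± 12.2 CPM (SD, n = 4; 2.88 ± 0.09, adjusted p = 4.51e-17). Klf9 rose by 2.47 ± 0.12, the clock gene Per1 by 1.75 ± 0.09 and Tsc22d3 by 1.70 ± 0.11. Larger rises were those of Jaml by 4.94 ± 0.28, Cd163 by 4.40 ± 0.26, F13a1 by 4.32 ± 0.41 and Ddit4 by 3.33 ± 0.40. Among the falls were Arg1 (−7.49 ± 1.89, adjusted p = 0.011), Mgl2 (−7.25 ± 1.44), the cadherin Cdh1 (−4.03 ± 0.72), the transcription factor Egr2 (−3.84 ± 0.66) and Myrf (−3.72 ± 0.44). Without the 4 libraries high in Arg1, Arg1 was at −3.65 (adjusted p = 0.0873), Mgl2 at −4.64, Cdh1 at −2.15 and Egr2 at −2.51. Corticosterone raised 877 and lowered 885 genes, and the 1762 calls became 941 without the 4 libraries high in Arg1 and 2974 with the replicate block. IL4 genes fell in 21 of 32 cases and rose in 1 (24 and 1 adjusted over the list alone), with a median of −2.16 (camera adjusted p = 6e-09, 0.268 with an estimated correlation) that was −0.89 without the 4 libraries. Receptor targets rose in 10 and fell in 4 of 30 (10 and 4 adjusted over the list alone; camera adjusted p = 0.000471). Class II genes fell in 7 of 11 cases (7 adjusted over the list alone), with Ciita at −2.06 ± 0.28 (camera adjusted p = 0.000711, 0.144 with an estimated correlation). Efferocytosis genes rose in 10 and fell in 6 of 27 cases (12 and 6 adjusted over the list alone), as Mertk (1.15 ± 0.10) and Stab1 (1.10 ± 0.11; camera adjusted p = 0.00661, 0.0899 with an estimated correlation). B cell transcripts fell in 3 of 6 cases (4 adjusted over the list alone), with Ighm at −2.02 ± 0.31 (camera adjusted p = 0.00172, 0.101 with an estimated correlation).

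Dexamethasone in knockout cells raised Jaml by 7.35 ± 0.28 (adjusted p = 2.65e-15), Ddit4 by 5.06 ± 0.41, F13a1 by 5.03 ± 0.42 and Cd163 by 4.82 ± 0.26. It raised Zbtb16 by 3.84 ± 0.21, Pik3ip1 by 3.73 ± 0.23 and Fkbp5 by 3.51 ± 0.09. It lowered Myrf (−3.52 ± 0.43), Ch25h (−2.98 ± 0.34), Tnip3 (−2.89 ± 0.11), Ighm (−2.79 ± 0.34) and the elastase gene Mmp12 (−2.72 ± 0.39). Of the genes tested 1328 rose and 1356 fell, 551 of them at least 2-fold, and the 2684 calls became 1789 without the 4 libraries high in Arg1. Receptor targets rose in 10 of 30 cases and fell in 5 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00201, 0.0526 with an estimated correlation). Efferocytosis genes rose in 12 and fell in 6 of 27 (13 and 7 adjusted over the list alone; camera adjusted p = 0.0129, 0.171 with an estimated correlation). Proinflammatory genes fell in 11 and rose in 4 of 27 (11 and 4 adjusted over the list alone; camera adjusted p = 0.012, 0.57 with an estimated correlation). Among the latter, Icam1 was at −0.97 ± 0.06 and Cd40 at −1.94. B cell transcripts fell in 3 of 6 cases (4 adjusted over the list alone; camera adjusted p = 0.00297, 0.171 with an estimated correlation). IL4 genes fell in 14 and rose in 2 of 32 cases (20 and 4 adjusted over the list alone), with a median of −1.23 (camera adjusted p = 0.00495, 0.595 with an estimated correlation). Without the 4 libraries high in Arg1 that median was −0.40 (adjusted p = 0.128). Class II genes fell in 5 of 11 cases (7 adjusted over the list alone), with a median of −0.55 (camera adjusted p = 0.0231, 0.566 with an estimated correlation). This became −0.43 (adjusted p = 0.105) without the 4 libraries, and the call was also lost without the knockout dexamethasone library numbered 3 (−0.45).

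In knockout cells, too, some genes moved in the same direction with IL4 and glucocorticoid. Klf9 rose with all treatments (2.16 with IL4, 2.47 with corticosterone, 3.42 with dexamethasone), Ms4a4a rose by 0.89 with IL4 (1.43 without the 4 libraries high in Arg1) and 1.25 with corticosterone, and the histone demethylase Kdm6b by 0.75 and 0.60. With IL4 and dexamethasone Htr2a rose by 2.12 and 1.39 and the guanine deaminase Gda by 1.41 and 1.25, while Nptx1 (−3.07 and −1.76), Cav1 (−1.99 and −1.65), Pilra (−1.64 and −1.51) and Gpr84 (−1.61 and −1.32) fell. IL4 and corticosterone shared 146 genes in knockout (74 up and 72 down, independent 127.4 and 106.3) and moved 706 in opposite directions (independent 234). IL4 and dexamethasone shared 473 (191 up and 282 down, independent 193 and 162.9) and moved 662 oppositely (independent 356.6). Both glucocorticoids shared 1497 (784 up and 713 down, independent 79.8 and 82.3), with 0 opposite. With the 4 knockout vehicle libraries split so that each treatment had its own 2, the medians over 6 splits were 59 (49 to 81), 230 (210 to 253) and 750 (682 to 778) shared genes. Fewer vehicle libraries also gave fewer calls, as rises with IL4 went from 2120 to between 1286 and 1967. The splits thus do not separate the effect of shared controls from that of fewer libraries. Covariances were −0.0976 (simulated 0.0348, difference −0.1324), −0.0363 (0.0345, difference −0.0708) and 0.2133 (0.0361, difference 0.1772), and r was −0.326, −0.116 and 0.792. The 146 became 96 and the 473 became 306 without the vehicle library numbered 1, and with the replicate block the counts were 393, 884 and 2468. With only the groups compared in the fit the 146 became 63 and the 473 became 218, and with no filter the 146 became 90. The libraries high in Arg1 include 2 knockout vehicle libraries. Without the 4, IL4 and corticosterone shared 223 genes (71 up and 152 down, independent 52.8 and 69.2) with 319 opposite (independent 121.7), with r at 0.056 and a covariance of 0.0219. IL4 and dexamethasone then shared 491 (160 up and 331 down, independent 105.5 and 126.3) with 398 opposite (independent 231.5), with r at 0.159 and a covariance of 0.0749. Both glucocorticoids shared 876 (395 up and 481 down, independent 22.9 and 34.7), with 0 opposite and r at 0.822.

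Knockout cells with vehicle held far lower levels of transcripts typical of stromal cells and neutrophils than wild-type cells. The collagen gene Col1a1 was at 188 ± 141 CPM (SD, n = 3) in wild type and 5.59 ± 1.98 (SD, n = 4) in knockout (−5.08 ± 0.74). The neutrophil protein gene S100a9 was at 73.4 ± 53.7 and 2.34 CPM (−5.03 ± 0.65). Other falls were in lactoferrin, Ltf (−5.91 ± 0.69), the smooth muscle genes Actg2 (−5.64 ± 0.82) and Tagln (−5.39 ± 0.80), Vgll3 (−5.39 ± 0.81) and the granule gene Ngp (−5.37 ± 0.70). Stromal markers fell in 14 of 15 cases (14 adjusted over the list alone; camera adjusted p = 2.79e-10, 0.25 with an estimated correlation). Neutrophil markers fell in 8 and rose in 1 of 13 (11 and 1 adjusted over the list alone; camera adjusted p = 2.36e-05, 0.303 with an estimated correlation). Those of monocytes fell in 7 of 11 cases (7 adjusted over the list alone), as F13a1 did (−2.67; camera adjusted p = 9.62e-05, 0.25 with an estimated correlation). Glycolysis genes fell in 14 of 19 cases (16 adjusted over the list alone), among them the lactate exporter Slc16a3 (−1.30 ± 0.14) and the glucose transporter Slc2a1 (−0.89 ± 0.11; camera adjusted p = 1.56e-10, 0.185 with an estimated correlation). Matrix genes fell in 13 and rose in 3 of 31 (15 and 3 adjusted over the list alone), as Mmp9 (−2.58) and Vegfa (−2.35; camera adjusted p = 0.000292, 0.403 with an estimated correlation).

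Among rises with vehicle, Ms4a4a was higher in knockout by 2.69 ± 0.23 (adjusted p = 3.88e-08), Mrc1 by 1.39 ± 0.20 and Tsc22d3 by 0.84 ± 0.12. The lectin Mgl2 (6.67 ± 1.49) and the coagulation factor gene F7 (2.65 ± 0.53) also rose, and were at 4.04 and 1.65 without the 4 libraries high in Arg1. MHC class II genes rose in 8 of 11 cases (8 adjusted over the list alone), with Ciita at 2.57 ± 0.32 (camera adjusted p = 9.55e-06, 0.185 with an estimated correlation). IL4 genes rose in 18 and fell in 2 of 32 cases (21 and 2 adjusted over the list alone), with a median of 1.79 (camera adjusted p = 0.000223, 0.492 with an estimated correlation). This median was 1.17 without the knockout vehicle library numbered 2 and 0.49 (adjusted p = 0.0538) without the 4 libraries high in Arg1. Retnla had 0 counts in wild type and 219 in knockout, at least 49.2-fold more (adjusted p = 0.0272). Its adjusted p was 0.0746, 0.077 and 0.0649 without the wild-type vehicle libraries numbered 1, 2 and 3, 0.0669 without the knockout vehicle library numbered 2, 0.138 without all wild-type libraries numbered 1, and 1 without the 4 libraries high in Arg1. Fkbp5 (0.05 ± 0.09, adjusted p = 0.794) and the glucocorticoid receptor gene Nr3c1 (−0.07, adjusted p = 0.72) did not differ. With vehicle 1236 genes were higher and 1502 lower in knockout, 1123 of them at least 2-fold, and the 2738 calls became 1809 without the wild-type vehicle library numbered 1, 1680 without the 4 libraries high in Arg1 and 1641 with only the groups compared in the fit.

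The stromal and neutrophil difference was also present after each treatment. Stromal markers fell in 13 of 15 cases with IL4, corticosterone and dexamethasone (14 adjusted over the list alone in each; camera adjusted p = 4.9e-09, 2.49e-10 and 3.86e-10, and 0.411, 0.247 and 0.271 with an estimated correlation). Neutrophil markers fell in 9, 8 and 8 of 13 and rose in 1, 0 and 1 (10, 9 and 10 lower and 2, 1 and 2 higher adjusted over the list alone; camera adjusted p = 0.000627, 5.45e-05 and 0.00192, and 0.411, 0.318 and 0.417 with an estimated correlation). Monocyte markers fell in 8 of 11 with corticosterone and with dexamethasone (9 adjusted over the list alone in each; camera adjusted p = 8.57e-06 and 6.72e-05, and 0.221 and 0.271 with an estimated correlation). Glycolysis genes fell in 6, 8 and 9 of 19 and rose in 0, 0 and 1 (10, 10 and 13 lower and 0, 0 and 1 higher adjusted over the list alone). Camera's adjusted p was 2.97e-06, 2.57e-05 and 9.44e-06 for them, and 0.411, 0.292 and 0.297 with an estimated correlation. Their member Slc16a3 was at −0.65 (−0.41 without the knockout IL4 library numbered 4), −0.87 and −0.99. Ltf (−4.75 with IL4, −4.78 with corticosterone, −5.32 with dexamethasone) and Col1a1 (−5.37 with IL4, −4.87 with corticosterone) were among the genes that fell.

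Genes of other kinds also differed between genotypes, and Kif21a, Acaa1b, Hddc3 and Parvg were higher in knockout in all 4 conditions. With IL4, Ccn3 was higher in knockout by 4.31 ± 0.46, the kinesin gene Kif21a by 3.22 ± 0.30, Gpr141 by 1.64 ± 0.14 and Hddc3 by 1.64 ± 0.13. The IL4 markers Arg1 (−0.53 ± 1.2, adjusted p = 0.809), Retnla (0.23 ± 0.50, adjusted p = 0.805) and Mrc1 (0.24 ± 0.21, adjusted p = 0.476) did not differ. With corticosterone, Acaa1b was higher by 5.07 ± 0.53, Gpr141 by 1.76 ± 0.12 and the adhesion gene Parvg by 1.75 ± 0.07 (adjusted p = 1.89e-14), and Chil3 lower (−3.55 ± 0.68, adjusted p = 0.0011). With dexamethasone, Kif21a was higher by 2.78 ± 0.28, Calml4 by 2.61 ± 0.26, Acpp by 2.16 ± 0.25 and Parvg by 1.86 ± 0.07. Fkbp5 was at −0.21 ± 0.09 with corticosterone and −0.20 ± 0.09 with dexamethasone (adjusted p = 0.124 in both). Receptor targets were lower in 11 and higher in 3 of 30 cases with dexamethasone (12 and 3 adjusted over the list alone), such as the phosphatase Dusp1 (−1.40 ± 0.25) and the kinase inhibitor Errfi1 (−1.38; camera adjusted p = 0.000357). No test compared conditions. With corticosterone 7 receptor targets were lower and 2 higher (11 and 3 adjusted over the list alone; camera adjusted p = 0.0023, 0.138 with an estimated correlation). With vehicle 11 were lower and 4 higher (11 and 4 adjusted over the list alone; camera adjusted p = 0.126), and with IL4 5 and 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.346). Errfi1 was at −0.95 with vehicle (adjusted p = 0.129 without wild-type vehicle library 1). It was at −1.26 with IL4 (adjusted p = 0.0844 without wild-type IL4 library 1) and −1.30 with corticosterone. From wild-type library 1 to 3, mean log2 CPM of receptor targets fell from 4.68 to 4.43 with vehicle and 5.42 to 5.22 with corticosterone. Stromal (5.42 to 3.90 with vehicle) and neutrophil markers (4.06 to 2.27) also fell. Other cells are thus not excluded as a source in these groups. With dexamethasone the list fell little (5.605 to 5.544), but other cells are not excluded for single members. Tsc22d3 went against the list and was higher with dexamethasone (0.48 ± 0.11). With IL4 840 genes were higher and 962 lower in knockout, with corticosterone 797 and 1305, and with dexamethasone 978 and 1534. The 1802 calls with IL4 became 638 without wild-type IL4 library 1 and 1015 without knockout IL4 library 4. They became 1016 without all wild-type libraries numbered 1 and 616 with only the groups compared in the fit. The 2102 calls with corticosterone became 1057 without wild-type corticosterone library 1 and 1270 without all wild-type libraries numbered 1. The 2512 calls with dexamethasone became 1540 without wild-type dexamethasone library 1 and 1378 without the 4 libraries high in Arg1.

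**Figure D4:**
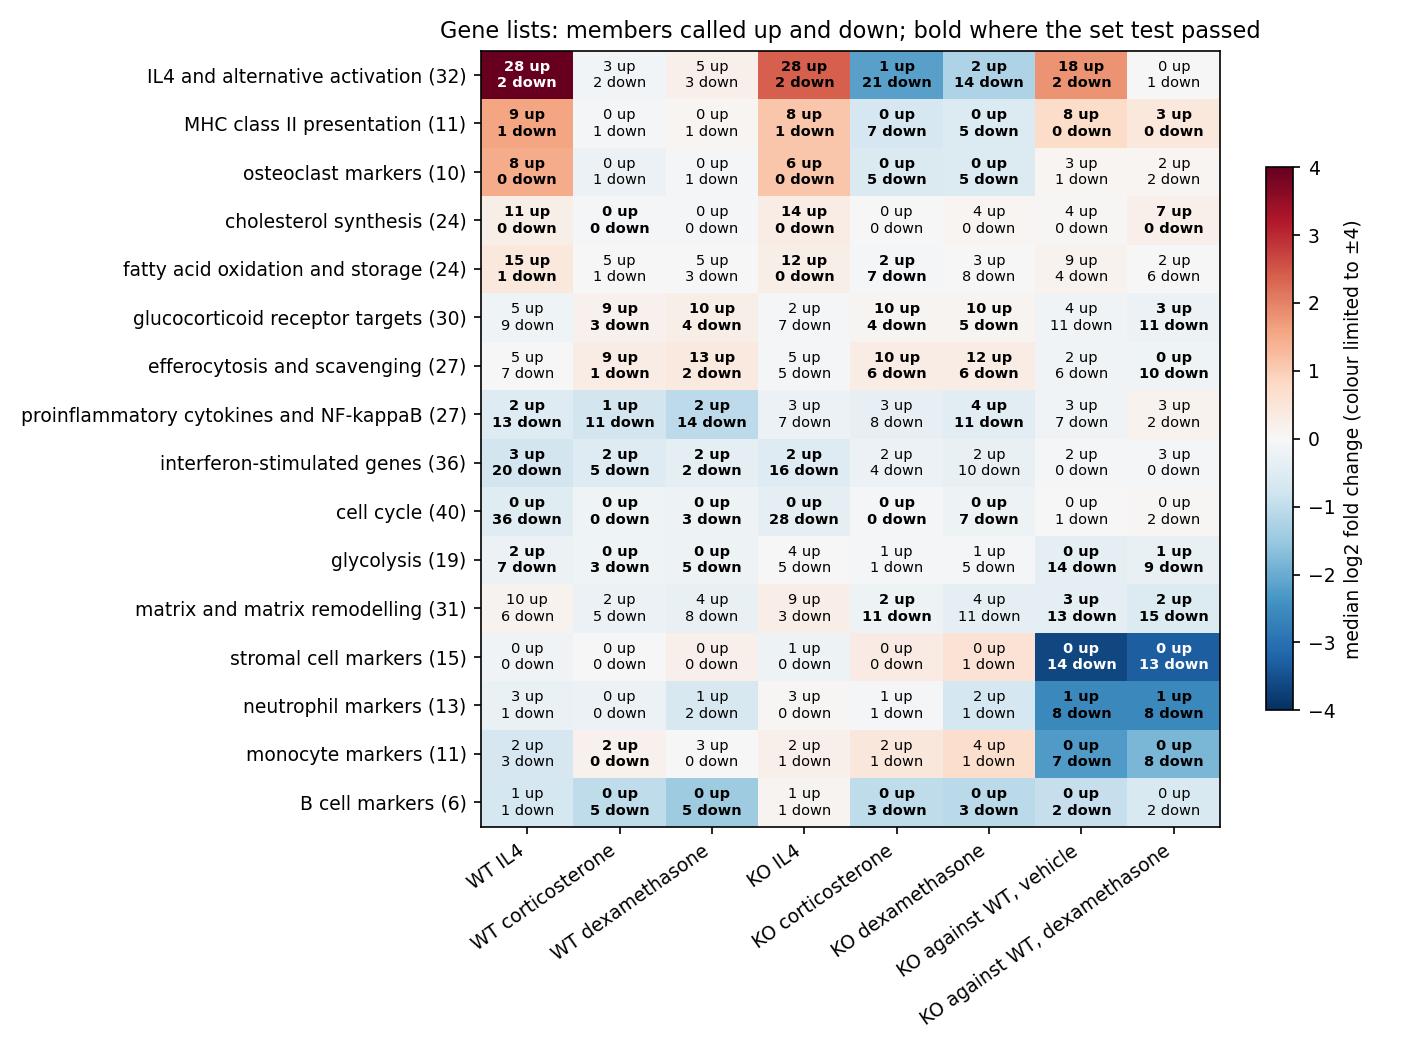
Gene lists (y axis, with their number of genes) against 8 comparisons (x axis), coloured by the median log2 fold change of the list, with the numbers of genes called up and down and bold text where camera's adjusted p passed. IL4 genes have 28 of 32 called up with IL4 in wild type, and stromal markers 14 of 15 called down in knockout against wild type with vehicle.

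Some genes responded to a treatment by a different amount in knockout cells. Ms4a4a rose less in knockout with corticosterone (interaction −2.10 ± 0.30, adjusted p = 0.00461) and dexamethasone (−2.17 ± 0.30, adjusted p = 0.000862). Its vehicle level was 153 ± 64.6 CPM (SD, n = 4) in knockout and 23.7 ± 2.39 (SD, n = 3) in wild type. The lipoprotein lipase gene Lpl (chromosome 8, 68880491 to 68907448) had interactions of −1.16 ± 0.17 (adjusted p = 0.00461) with corticosterone and −1.57 ± 0.17 (adjusted p = 5.56e-05) with dexamethasone. Its levels were 1938 ± 291 CPM with vehicle and 491 ± 68.0 with dexamethasone in knockout (SD, n = 4), and 1491 ± 265 and 1118 ± 86.4 in wild type (SD, n = 3). With dexamethasone the adaptor gene Ppfibp2 (0.88 ± 0.12) and the galactosyltransferase Ggta1 (0.49 ± 0.07) also differed. Without the wild-type libraries numbered 1 the adjusted p was 0.0768 for Ms4a4a and Lpl with corticosterone and 0.0586 for Ms4a4a and 0.0598 for Ggta1 with dexamethasone, and without the 4 libraries high in Arg1 it was 0.0566 for Ggta1. With only the groups compared in the fit it was 0.0788 for Ms4a4a with corticosterone and 0.0694 with dexamethasone. Fkbp5 did not differ (−0.25 ± 0.12, adjusted p = 0.873 with dexamethasone and 0.792 with corticosterone).

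Interaction tests called 4 genes for IL4, 3 for corticosterone and 27 for dexamethasone, with 1323, 926 and 880 genes at an unadjusted p under 0.05. These counts depended on the test, as DESeq2 called 79, 78 and 80. With the replicate number as a block they were 149, 110 and 214, where the pairs passed in both genotypes for corticosterone alone. With only the groups compared in the fit they were 0, 13 and 10. The 4 calls for IL4 became 0 without the wild-type vehicle library numbered 1 or 3, the wild-type IL4 library numbered 2, the knockout vehicle library numbered 3 or the knockout IL4 library numbered 2. They became 2 without wild-type vehicle library 2 or knockout IL4 library 4, and 1 without knockout vehicle library 2. The count rose to 9 without wild-type IL4 library 1, 8 without knockout IL4 library 1 and 95 without knockout vehicle library 1. The 3 calls for corticosterone became 36 and 9 without the knockout vehicle libraries numbered 1 and 4. The 27 calls for dexamethasone became 17 and 16 without the wild-type vehicle libraries numbered 1 and 3, and 17 and 15 without the wild-type dexamethasone libraries numbered 1 and 2. They became 17 and 16 without knockout vehicle libraries 2 and 3, and 17 without knockout dexamethasone library 1. Without the 4 libraries high in Arg1 the counts were 2, 5 and 12, and without the wild-type libraries numbered 1 they were 0, 0 and 3.

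All 3 interactions subtract the same vehicle difference between the genotypes, so they are not independent results. With vehicle, IL4 genes were more often higher than lower in knockout, which alone lowers their interactions. As a group, IL4 genes had a median interaction of −1.79 with IL4, and −0.72 without the 4 libraries high in Arg1. For them 0 were called, and 22 were lower and 0 higher adjusted over the list alone (camera adjusted p = 1.1e-10, 0.383 with an estimated correlation). With corticosterone their median was −1.64, and −0.70 without the 4 libraries. There 0 were called, and 19 were lower and 1 higher adjusted over the list alone (camera adjusted p = 1.28e-11, 0.258 with an estimated correlation). With dexamethasone their median was −1.25 (0 called, 6 lower adjusted over the list alone, camera adjusted p = 9.45e-08, 0.406 with an estimated correlation) and, without the 4 libraries, −0.32 (adjusted p = 0.0511). Genes of fatty acid oxidation and storage, which include Lpl, had a median of −0.18 with IL4 (0 called, 0 adjusted over the list alone, camera adjusted p = 1.36e-05). Their medians were −0.15 with corticosterone (1 called lower, 4 adjusted over the list alone, camera adjusted p = 8.82e-08) and −0.155 with dexamethasone (2 called lower, 4 adjusted over the list alone, camera adjusted p = 5.81e-08). Without the 4 libraries the 3 medians were −0.11, −0.085 and −0.087. Class II genes had a median of −0.80 with IL4, and −0.41 without the 4 libraries (0 called, 4 lower adjusted over the list alone, camera adjusted p = 6.12e-07, 0.0525 with an estimated correlation). Interactions of proinflammatory genes lay above those of other genes by camera with corticosterone (0 called, 0 adjusted over the list alone) and with dexamethasone (0 called, 1 higher adjusted over the list alone), with camera adjusted p = 2.7e-07 and 5.48e-07 (0.228 and 0.26 with an estimated correlation). This compares the responses of the genotypes and is not a rise with either drug.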

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

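The tests of the libraries high in Arg1 and of the stromal and neutrophil genes were chosen after their results were seen, while the splits of the libraries were planned.

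Glucocorticoid and IL4 responses of some genes differed between genotypes by the interaction test, which is what singled them out here. With IL4 these 4 genes were the kinase gene Pdk1 (0.54), Map2 (−2.60), Ms4a4a (−1.97) and Arhgap25 (−0.77). With corticosterone the 3 genes were Ppfibp2 (0.755), Ms4a4a (−2.10) and Lpl (−1.16). With dexamethasone, 27 genes in number, the examples were the leukotriene enzyme Alox5 (1.04), Pde4b (0.90), Ppfibp2 (0.88), Osgin1 (0.64) and Ggta1 (0.49) on the higher side, and Ms4a4a (−2.17), Lpl (−1.57), Zbtb16 (−1.56) and Dlg3 (−1.37) on the lower side. Gene lists whose interaction differed from other genes by camera had these medians, where all 3 interactions use the same vehicle libraries. With IL4 they were −1.79 for IL4 genes, 0.25 for proinflammatory genes, −0.80 for MHC class II, 0.21 for glycolysis, −0.18 for fatty acid genes, −0.17 for oxidative phosphorylation, −0.44 for osteoclast markers and −0.14 for ribosomal proteins. With corticosterone they were −1.64 for IL4 genes, 0.41 for proinflammatory genes, 0.23 for interferon-stimulated genes, −0.53 for MHC class II, 0.075 for cholesterol synthesis, 0.175 for glycolysis, −0.15 for fatty acid genes and −0.39 for osteoclast markers. With dexamethasone they were −1.25 for IL4 genes, 0.375 for proinflammatory genes, −0.47 for MHC class II, 0.13 for cholesterol synthesis, 0.13 for glycolysis, −0.155 for fatty acid genes, −0.225 for the integrated stress response and −0.091 for ribosomal proteins. Of these lists, the fatty acid genes alone stayed called with an estimated correlation. Medians with IL4, without the 4 libraries high in Arg1, were −0.72 for IL4 genes, −0.41 for MHC class II, −0.11 for fatty acid genes and −0.10 for oxidative phosphorylation. With corticosterone those of IL4 genes became −0.70, MHC class II −0.29, cholesterol synthesis 0.168, fatty acid genes −0.085, osteoclast markers −0.235 and interferon-stimulated genes −0.061 (adjusted p = 0.474). With dexamethasone they became −0.32 for IL4 genes (adjusted p = 0.0511), −0.16 for MHC class II (0.483), 0.014 for the integrated stress response (1), −0.01 for ribosomal proteins (0.942), 0.20 for cholesterol synthesis and −0.087 for fatty acid genes. Without the wild-type libraries numbered 1, cholesterol synthesis with corticosterone was at 0.032 (adjusted p = 0.425), and with dexamethasone the integrated stress response was at −0.127 and ribosomal proteins at −0.09 (adjusted p = 0.0573). Calls also ended without at least 1 single library for glycolysis and ribosomal proteins with IL4, for cholesterol synthesis, osteoclast markers and interferon-stimulated genes with corticosterone, and for MHC class II, the integrated stress response and ribosomal proteins with dexamethasone. Of 100 drawn regroupings of the libraries, 10, 9 and 13 gave as many calls as the 4, 3 and 27 genes (the real grouping included), so chance was not excluded. The highest counts among the others were 2295, 3149 and 3429. Regrouping can carry the difference between the genotypes into the interaction, so these may reflect that difference. Lpl and Ppfibp2 with dexamethasone stayed called without any 1 library and without either set of 4 libraries. The other genes named here each lost their call in at least 1 of these settings. With dexamethasone, Zbtb16 also lost it with no filter (adjusted p = 0.0584), and Zbtb16 (0.113) and Pde4b (0.0595) lost it with the edgeR 4 fit. With only the groups compared in the fit, adjusted p was 0.17 for Zbtb16, 0.193 for Pde4b and 0.345 for Dlg3.

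Single libraries stood apart from the other 3 of their group in 9 of 126 tests, where chance alone singles out about 1 in 20 groups. In knockout cells with vehicle, Ncoa3 was at 196 CPM in the library numbered 2, the mean log2 CPM of MHC class II genes was 4.05 in the one numbered 1, that of oxidative phosphorylation genes 7.25 in the one numbered 2, and that of chemokine and cytokine receptors 6.21 in the one numbered 4. With corticosterone, monocyte markers averaged 1.36 in the library numbered 3 and stromal markers 1.10 in the one numbered 1. With dexamethasone, Retnla was at 0.59 CPM and endothelial markers averaged 2.01 in the library numbered 2, and monocyte markers averaged 1.88 in the one numbered 1.

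Arg1, Mgl2 and other IL4 genes were high in 4 libraries not given IL4. Reads from IL4-treated libraries mixed in would lower and raise genes by one share, but the share implied by IL4-lowered genes was at least 2.14 times that implied by IL4-raised genes in each of the 4, which argues against mixing as the whole source. An exchange of labels with an IL4 library was also argued against, since Retnla reached at most 0.0289 of its level in the lowest IL4 library of the genotype. Partial activity of the IL4 pathway in these cultures may remain, as at least 74.6% of 477 genes lowered by IL4 lay below the other libraries of the group (49.0 to 51.2% of other genes), but in 1 library this fell short of the share set for it and no treatment of these cultures with IL4 is recorded, so it stays open.

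Stromal and neutrophil genes were lower in knockout than in wild-type libraries. Lower depth of the knockout libraries was argued against, with a ratio of median totals of 1.04. More stromal and neutrophil cells carried along in the wild-type cultures is a candidate explanation. Of 886 further genes lower in knockout with vehicle, 80.5% were higher in the wild-type libraries numbered 1 than in those numbered 3 under all 3 other treatments, against 22.4% of other genes. The choice of these genes favours that outcome. The wild-type vehicle library numbered 1 took part in selecting them, and same-numbered wild-type libraries correlated across treatments. The share thus does not settle the explanation. A change of expression in macrophages lacking GRIP1 cannot be told apart from it. Wild-type vehicle libraries numbered 1 and 3 already differed 3.72-fold in the stromal and 3.86-fold in the neutrophil list with no change of genotype. Which animals the cultures came from is not given.

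Genes called between genotypes in one direction in all 4 conditions numbered 241 higher and 648 lower. DNA of another strain carried along around the targeted Ncoa2 locus could place such genes near it, and the share called within 10 Mb of Ncoa2 was 2.15 times that elsewhere (6 of 46 against 882 of 14536, Fisher's exact test, two-sided, p = 0.0589). Near Lyz2, the locus of Cre, the ratio was 2.30 (11 of 79 against 878 of 14503, Fisher's exact test, p = 0.00819), a test that was not planned. By direction, Fisher's exact p for lower genes was 0.00821 near Lyz2 (9 of 79) and 0.052 near Ncoa2 (5 of 46). For higher genes it was 0.376 (2 of 79) and 0.536 (1 of 46). The genes lower in all 4 conditions include stromal ones such as Col1a1. These ratios thus do not tell DNA of another strain from the stromal difference. If the wild-type animals also carried LysM-Cre, as their labelled genotype says, DNA around Lyz2 would not differ between the genotypes. Tlr8, Tlr7, Prps2, Msl3, Arhgap6 and Hccs, close together on chromosome X, were also higher in all 4 conditions (Tlr7 by 1.41 with IL4). So was Mid1-ps1 on chromosome Y. Other regions, strain and variants were not analysed, so this stays open.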

How the results depend on the processing

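The 2 settings that leave out sets of 4 libraries were chosen after the data were seen. RLE scaling changed no call of a list or named gene and moved no count of calls by over 1.5 times (the 1802 for genotype with IL4 became 1654), and no gene reversed under any alternative run. Of the lists, 3 interaction medians changed sign. Interferon-stimulated genes with corticosterone went from 0.233 to −0.061 and integrated stress response genes with dexamethasone from −0.225 to 0.014 without the 4 libraries high in Arg1. Ribosomal proteins with dexamethasone went from −0.091 to 0.005 without knockout vehicle library 2 (range over single libraries −0.142 to 0.005). Of the named genes DESeq2 left 1 uncalled. Where a value moved, the cause was not tested, except that a 2-fold minimum can only lower a count.

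DESeq2 called 79, 78 and 80 genes for the interactions with IL4, corticosterone and dexamethasone, and 57 and 164 for dexamethasone against corticosterone in wild type and knockout. The edgeR 4 fit called 7 for the IL4 interaction and 42 for dexamethasone against corticosterone in wild type. With at least 1 CPM in 3 libraries the corticosterone interaction had 6 calls. With no filter the IL4 interaction had 8, and IL4 and corticosterone shared 90 in knockout. With at least 2-fold changes in both, the shared counts were 64, 135 and 198 in wild type (IL4 with corticosterone, IL4 with dexamethasone, both glucocorticoids) and 12, 56 and 299 in knockout. Split vehicle libraries gave 59, 230 and 750 in knockout.

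With only the groups compared in the fit, counts were 1329 for dexamethasone in wild type, 1745 for IL4 in knockout, 1641 and 616 for genotype with vehicle and IL4, 0 (edgeR, where DESeq2 on all groups called 79 and 1323 had an unadjusted p under 0.05 in edgeR), 13 and 10 for the interactions, 10 and 80 for dexamethasone against corticosterone, and 63 and 218 for genes shared by IL4 with corticosterone and dexamethasone in knockout.

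With the replicate number as a block, counts rose for corticosterone and dexamethasone in wild type (1790, 3225) and knockout (2974, 4056), the interactions (149, 110, 214), dexamethasone against corticosterone (137, 274) and shared genes in wild type (746, 1329, 1701) and knockout (393, 884, 2468), and it moved no other count by over 1.5 times. Pair correlations that did not pass were 0.02 to 0.44 for IL4 and −0.23 to 0.47 for dexamethasone against vehicle in knockout, and −0.44 to −0.01 (vehicle), −0.24 to −0.22 (IL4), −0.21 to 0.03 (corticosterone) and −0.41 to 0.20 (dexamethasone) between genotypes.

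Without the 4 libraries high in Arg1, counts were 941 and 1789 for corticosterone and dexamethasone in knockout, 1680 and 1378 for genotype with vehicle and dexamethasone, 2, 5 and 12 for the interactions, 53 and 101 for dexamethasone against corticosterone, and 223 and 876 for genes shared in knockout by IL4 with corticosterone and by both glucocorticoids. Without the wild-type libraries numbered 1, they were 486 for corticosterone in wild type, 1016 and 1270 for genotype with IL4 and corticosterone, 0, 0 and 3 for the interactions (edgeR), 14 for dexamethasone against corticosterone, and 175, 489 and 478 for shared genes in wild type.

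Leaving out 1 library at a time gave 3493 to 4292 calls for IL4, 497 to 690 for corticosterone and 1327 to 1850 for dexamethasone in wild type, and 2767 to 3995, 1250 to 1814 and 2106 to 2805 in knockout. Between genotypes the ranges were 1809 to 2773 (vehicle), 638 to 1951 (IL4), 1057 to 1938 (corticosterone) and 1540 to 2285 (dexamethasone), and for the interactions 0 to 95, 2 to 36 and 15 to 36. Dexamethasone against corticosterone gave 10 to 39 in wild type and 19 to 49 in knockout, IL4 against corticosterone 3737 to 4351 and against dexamethasone 3561 to 4724. Shared counts were 201 to 330, 530 to 713 and 492 to 845 in wild type, and 96 to 172, 306 to 552 and 1091 to 1527 in knockout.

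At this depth Retnla at 0 counts in wild-type vehicle libraries allows a level up to 0.0336 CPM over the group, and 1.5-fold changes were recovered less often than 2-fold ones in simulated counts.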

Other observations

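The opposite genes were chosen after their values were seen, and the splits of the libraries were planned.

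IL4 and dexamethasone moved some immune genes in opposite directions in wild-type cells. The MHC class II regulator Ciita rose by 4.51 ± 0.33 with IL4 and fell by 1.73 ± 0.51 with dexamethasone. That fall of Ciita was not called without the vehicle library numbered 3 (−1.37, adjusted p = 0.141), nor without the dexamethasone library numbered 2 (−1.66, adjusted p = 0.0932) or 3 (−1.41, adjusted p = 0.141). The elastase gene Mmp12 (2.24 ± 0.44 and −1.98 ± 0.44), the amino acid transporter Slc36a2 (1.93 ± 0.16 and −2.10 ± 0.18) and the granzyme inhibitor Serpinb9b (2.88 ± 0.27 and −1.79 ± 0.31) went the same way as Ciita. The coagulation gene F13a1 (−2.03 ± 0.45 with IL4 and 3.18 ± 0.43 with dexamethasone), Prss16 (−2.75 ± 0.44 and 2.5 ± 0.35), the flagellin receptor Tlr5 (−2.76 ± 0.55 and 1.98 ± 0.41) and Notch4 (−1.74 ± 0.25 and 2.27 ± 0.22) went the other way. With only the groups compared in the fit, adjusted p was 0.0615 for F13a1 with IL4 and 0.0753 for Mmp12 with dexamethasone.

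Mitochondrial and translation genes moved little with IL4 in wild type. Oxidative phosphorylation genes rose in 12 of 36 cases (13 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 9.73e-05, 0.751 with an estimated correlation). Ribosomal protein genes had a median of 0.13 with 0 of 35 called and 0 adjusted over the list alone (camera adjusted p = 0.0288, 0.856 with an estimated correlation). Integrated stress response genes rose in 3 and fell in 1 of 20 cases, immediate early genes rose in 3 and fell in 5 of 20, and macrophage identity genes rose in 4 and fell in 5 of 18. Chemokine and cytokine receptors rose in 12 and fell in 10 of 32, and nuclear receptor coregulators rose in 5 and fell in 3 of 30 (median −0.06, mean 0.14). Adjusted over the list alone, 4 immediate early genes rose and 6 fell, 14 receptors rose and 10 fell, and the other 3 lists had the same numbers. Camera's adjusted p was 0.0699, 0.632, 0.145, 0.145 and 0.731 for these 5 lists, and for the integrated stress response it was 0.0305 without the 4 libraries high in Arg1 and 0.00987 without the wild-type libraries numbered 1.

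Markers of lymphoid, dendritic, endothelial, erythroid and mast cells were not called as groups by camera with IL4 in wild type. Dendritic cell markers rose in 2 and fell in 1 of 8 cases (camera adjusted p = 0.377) and T and NK cell markers rose in 2 of 4 (0.313), and the fry test called both lists higher (adjusted p = 0.00251 and 0.00438). B cell markers rose in 1 and fell in 1 of 6 (camera adjusted p = 0.534), endothelial markers rose in 2 and fell in 1 of 8 (0.752), and erythroid (0 of 4, 0.621) and mast cell markers (0 of 6, 0.752) were not called by edgeR. These numbers were the same adjusted over the list alone.

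Other splits of the same libraries were too few for a share under 0.05 in several comparisons. Where the replicate numbers paired the libraries, the real split was compared with splits that part as many pairs, 4 in wild type and 8 in knockout with the real one. In wild type the highest other gave 0 calls for IL4 (4388 in the real split), corticosterone (866) and dexamethasone (1996) against vehicle, for dexamethasone against corticosterone (27), and for IL4 against corticosterone (4628) and dexamethasone (4619). In knockout it gave 0 for corticosterone against vehicle (1762) and for dexamethasone against corticosterone (47, where a split that parts fewer pairs gave 16). For knockout against wild type with IL4 there were 10 splits (1802, highest other 5). In 5 comparisons with 35 splits only the real split gave as many calls, a share of 0.0286. In knockout these were IL4 (3873, highest other 3055) and dexamethasone (2684, 624) against vehicle. Between genotypes they were vehicle (2738, 2114), corticosterone (2102, 654) and dexamethasone (2512, 1171). That share is the smallest that 35 splits allow and was not adjusted over the comparisons, so chance was not excluded. For IL4 in knockout the 3055 came from setting the vehicle libraries numbered 1, 3 and 4 apart, and with vehicle the 2114 came from placing the knockout library numbered 1 with the wild-type ones.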
